A study of Mus musculus with 2 samples.

How the data were processed

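Tumour tissue from 1 control IgG and 1 SLC7A11 antibody library was dissociated with collagenase and DNase and profiled with a 10x Genomics 3' kit, per the labels' protocols. The deposited files are 2 tables of UMI counts per gene and barcode, made by the authors with Cell Ranger 7.2.0 against build mm10, and Seurat is named as a further tool, per the labels. All values were whole numbers, with 0 non-integer and 0 negative values in either table, and every barcode had at least 500 UMIs. The tables shared 28526 gene identifiers, with 3106 only in the control and 2768 only in the antibody table, and a gene absent from a table was taken as 0. Of 600 symbols in the gene and marker lists, 8 were not in the tables, of which 3 were matched through synonyms.

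Cells were kept with at least 200 genes, 500 UMIs and under 20% mitochondrial counts, which left 13863 control and 12061 antibody barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring cells were removed up to 0.8% per 1000 cells, 1537 in the control (11.1%) and 1164 in the antibody library (9.65%). Both libraries were clustered together without integration: scaling to 10000 counts, log transform, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1, which gave 25 clusters. Genes seen in at least 3 cells were used, scaled values were clipped at 10, neighbour weights were Jaccard overlaps above 1/15, Leiden ran for 5 iterations and the seed was 0. Leading genes of a cluster had to be detected in 20% of its cells. T-like cells were clustered again into 7 clusters. No correction for free RNA was made. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9 were used.

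Markers for 28 classes, the 29 gene lists, the rule for named genes, the comparisons and a set of alternative settings were chosen before the data were examined. The scoring rule that turns markers into names was set after seeing the data, over several tries. A cluster took the class with the best mean marker level, scores within 0.02 being decided by markers among its 10 leading genes. It stayed unnamed with a score under 0.25 (0.5 for T clusters), under 3 markers detected in 10% of cells, more leading genes of another class than of its own, or a median depth under 1/3 of its library's without a marker among the leading genes. Names of host cells needed at least 15% of the Y-linked level (4 genes) of the T, NK, macrophage and neutrophil clusters, and the tumour name needed less. T clusters with both CD8 and CD4 transcripts at 25% or more of the highest level stayed unnamed.

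Counts were summed per class and library for the 5 classes with at least 100 cells in each library: tumour-like, CD8 T-like, macrophage-like, neutrophil-like and fibroblast-like. CD4 T-like and NK-like cells fell under this minimum and were added after seeing the data, for list medians, the target genes and example genes of the lists. The log2 ratio used a prior count of 0.5 and the class total. No test across samples could be made with 1 library per group, so no p-value is given. Shares have exact Clopper-Pearson 95% intervals, ratios of counts exact conditional binomial intervals, and list medians 95% ranges over 1000 Poisson redraws. A ratio against 0 counts is given as a bound against a floor of 3 counts in the class sum. List medians used genes with at least 20 counts, at least 5 per list, and were ranked among 10000 random lists matched on expression in 20 bins. Named genes were, per class, the 10 highest and 10 lowest log2 ratios of at least 1 in size among genes with 100 counts, detected in 10% of cells of a library, with at least 0.1 of the highest level in any other class, leaving out mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes and gene models. Other genes were picked as examples from the lists after their values were seen.

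The alternative settings chosen in advance were a stricter cell filter (500 genes, 1000 UMIs, under 10% mitochondrial), no doublet removal, Leiden resolution 2, separate clustering of each library, T subsets by transcripts, median-of-ratios scaling, totals without mitochondrial, ribosomal and haemoglobin genes, cells thinned to 1000 UMIs (739 control and 1118 antibody cells were shallower), count minimums of 0 and 100, and means over scaled cells. Chosen after seeing the data were ratios minus the median of the other classes, unnamed clusters without Y-linked transcripts counted as tumour-like, unnamed clusters with macrophage as best or second score counted as macrophage-like, and decorin-high clusters counted as fibroblast-like. Alternatives were computed for classes with at least 50 cells per library, a minimum set after CD8 T-like cells fell below 100 under some of them. Which list medians count as main results was settled after the medians had been seen.

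The ratios were tested on simulated data, with counts drawn from the real class means and totals and 200 genes changed by known amounts. In the simulated tumour-like comparison of 13630 genes, genes set to log2 ratios of 1, -1, 2 and -2 had medians of 1.00, -1.03, 2.00 and -2.00, and the intervals covered the true value in 98.0%, 92.0%, 98.0% and 98.0% of 50 genes each. In the simulated CD8 T-like comparison of 3080 genes the medians were 0.92, -1.00, 2.00 and -2.07. In the simulated macrophage-like comparison of 7783 genes they were 1.01, -0.97, 2.01 and -2.02, and in the neutrophil-like one of 430 genes 0.99, -0.93, 2.05 and -1.94. Every changed gene lay on the right side of 0 (100% in each case), and a list of 20 changed genes ranked at the 100th percentile. That list held only genes set to a log2 ratio of 1, so a high rank was built in. Lists of 20 unchanged genes ranked at percentiles of 12.5 (tumour-like), 31.1 (CD8 T-like), 41.4 (macrophage-like) and 32.0 (neutrophil-like). Intervals covered unchanged genes in 95.2% (tumour-like), 96.5% (CD8 T-like), 95.9% (macrophage-like) and 96.5% (neutrophil-like) of cases. Simulated ratios were centred on the median gene, unlike the reported ones, and covered genes with at least 100 counts. The simulation held counting error only, without free RNA, a library-wide shift or a change in cell make-up, so it does not test for these. Transcript lengths, GC content and shared sequence came from the longest GENCODE transcript of each gene, in a release that may differ from the one behind the counts.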

Results

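The data were single-cell RNA counts from 2 libraries of mouse colon tumours, 1 per group. The tumours grew from CT26 cells, an established mouse colon carcinoma line. The study's design text places the injection at the caecum but also speaks of subcutaneous growth, so the site is uncertain here. Mice received control IgG or an antibody against SLC7A11, the cystine-importing subunit of the cystine/glutamate antiporter, at 10 mg/kg every 2 days from a tumour volume of 50 to 100 mm³. The control library held 13910 barcodes with 129044329 UMIs and the antibody library 12153 barcodes with 143658800 UMIs. After filtering and doublet removal, 12326 control and 10897 antibody cells remained, with median depths of 7052 and 7201 UMIs. With 1 library per group no difference has a replicate check. The 95% intervals given here, exact binomial for shares and exact Poisson or conditional binomial for counts, cover counting error only. Ratios are antibody over control.

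The first question was which cells made up the tumours after treatment. T-like cells were 1.42% of control cells and 6.88% of antibody cells, a share 4.85-fold higher in the antibody library (log2 ratio 2.28, interval 2.04 to 2.52). NK-like cells were 0.787% and 2.89%, plasmacytoid dendritic-like cells 0.211% and 0.853%, cDC1-like cells 0.146% and 0.321%, and mast-like cells 0.065% and 0.294%. Tumour-like cells were 64.9% of control cells (interval 64.0 to 65.7) and 39.7% of antibody cells (38.8 to 40.6). Their log2 ratio of -0.71 was smaller in size under every other filter or clustering, between -0.50 without doublet removal and -0.35 under a stricter cell filter. Macrophage-like cells were 6.38% and 8.64%, but without doublet removal their log2 ratio was -0.43 in place of 0.44, and it was 1.00 with unnamed clusters of high macrophage score counted in. Neutrophil-like cells were 1.12% and 2.08%, and their log2 ratio of 0.90 became -0.27 under a stricter cell filter. Fibroblast-like cells were 1.47% and 2.17%, a log2 ratio of 0.56 that was -0.18 without doublet removal, 1.59 under the stricter cell filter and 2.20 with each library clustered on its own. Endothelial-like cells were 0.300% and 0.275%, a difference within counting error. Clusters that carried Y-linked transcripts, which the tumour-like clusters nearly lack by the naming rule, held 14.2% of control cells (interval 13.6 to 14.9) and 33.9% of antibody cells (33.0 to 34.8).

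Clusters left unnamed held 23.3% of control cells and 35.9% of antibody cells. Among them were decorin-high clusters without Y-linked transcripts (15.3% and 13.5%), a hypoxia-led cluster (3.95% and 6.46%), a cluster led by Il1b and Lyz2 with MHC class II genes (1.05% and 5.85%), a low-UMI cluster led by Lyz2 and C1q genes (1.22% and 2.84%), a low-UMI cluster (1.69% and 6.40%) and a low-UMI cluster with T cell genes (0.065% and 0.808%). Within the cells of clusters with Y-linked transcripts, T-like cells were 9.98% and 20.3%, NK-like cells 5.53% and 8.53%, and plasmacytoid dendritic-like cells 1.48% and 2.52%. Other classes were lower on this base: neutrophil-like cells 7.87% and 6.15%, fibroblast-like cells 10.3% and 6.39%, and endothelial-like cells 2.11% and 0.812%. Differences for cDC1-like (1.03% and 0.948%) and mast-like cells (0.456% and 0.867%) were within counting error there. Macrophage-like cells were 44.8% and 25.5%. This macrophage-like share leaves out unnamed clusters whose best or second score was macrophage. They were the cluster led by Il1b and Lyz2 (7.36% and 17.2%) and that led by Lyz2 and C1q genes (8.56% and 8.37%). Part of the macrophage-like difference therefore depends on naming. Depth differed between the libraries within classes: the median was 9864.5 UMIs in control and 17429 in antibody tumour-like cells, and 1689 and 3051 in CD8 T-like cells. Different clusters held most of a class in each library: clusters 0, 1 and 2 of the control tumour-like cells against 3 and 5 of the antibody ones, and cluster 12 against cluster 9 of the macrophage-like cells. A cluster mostly from 1 library may be that library and not a cell type.

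**Figure D1:**
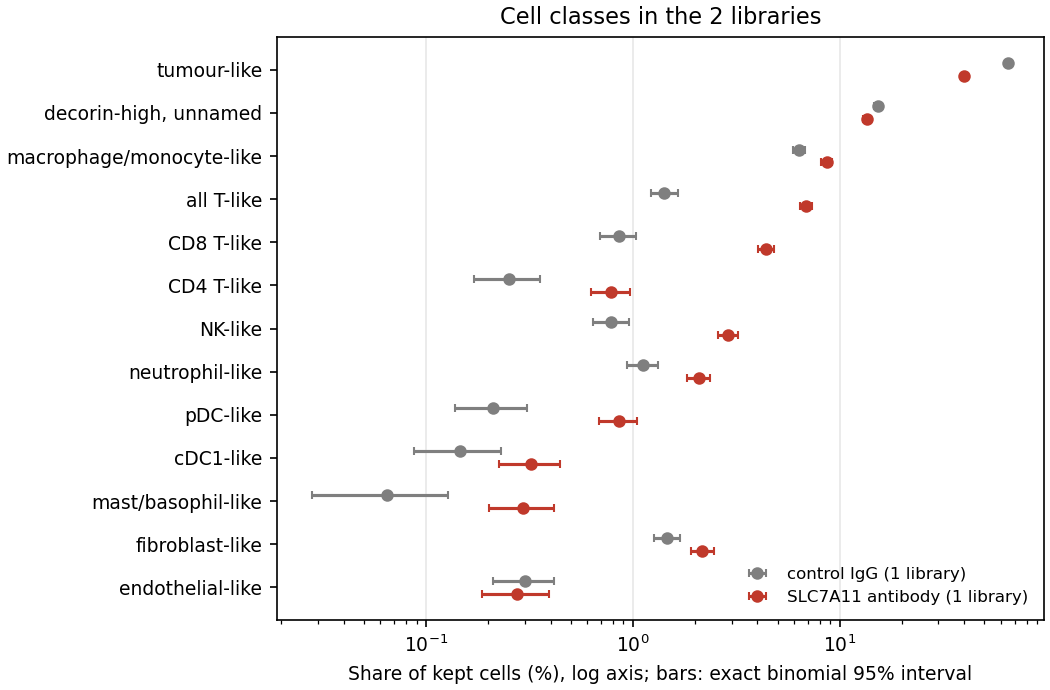
Share of kept cells (percent, log axis) per cell class in the control library (grey) and the antibody library (red), 1 library each, with exact binomial 95% intervals. T-like cells were 1.42% and 6.88%, and tumour-like cells 64.9% and 39.7%.

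The study's title concerns CD4 and CD8 T cells. CD8 T-like cells numbered 105 in the control and 479 in the antibody library, 0.852% and 4.40% of all cells. CD4 T-like cells, all in a regulatory T-like cluster led by Foxp3, numbered 31 and 85, or 0.252% and 0.780% of all cells. The share was also higher in the antibody library with T subsets set by transcripts (16 and 66 cells). With each library clustered on its own the numbers were 92 and 80, but that setting named 0 control CD8 T-like cells and so did not separate the subsets there. Among cells of clusters with Y-linked transcripts, CD4 T-like cells were 1.768% and 2.302%. That log2 ratio of 0.38 was within counting error (interval -0.229 to 1.023). CD8 T-like cells were 5.99% and 12.97% on the same base, with an interval of the log2 ratio from 0.807 to 1.433. Within T-like cells the CD8 share was 60.0% (interval 52.3 to 67.3) and 63.9% (60.3 to 67.3), a difference within counting error. With T subsets set by transcripts the gap was wider, at 50.9% and 66.5%. The CD4 share of T-like cells, counting only the regulatory T-like cluster, was 17.7% (12.4 to 24.2) and 11.3% (9.15 to 13.8). Its log2 ratio of -0.64 was 0.34 under a stricter cell filter. With T subsets set by transcripts it was -0.055, with CD4 shares of 9.14% and 8.80%. A further 22.3% and 24.8% of T-like cells stayed without a subset, mostly in a cluster with both CD8 and CD4 transcripts. Its level of CD4 transcripts was 322 CPM, against 200 CPM in the regulatory T-like cluster. The CD4 share may therefore leave out other CD4 cells.

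The antibody's target was read at the transcript level. In tumour-like cells Slc7a11 had 18.2 CPM in the control and 22.5 CPM in the antibody library (log2 ratio 0.31, interval 0.21 to 0.40). Neutrophil-like cells had the highest level among the compared classes, 584 and 804 CPM. In macrophage-like cells it was 25.8 and 23.6 CPM, and in CD8 T-like cells 1 count and 7 counts, a log2 ratio of -0.64 with an interval from -3.12 to 5.34. Over the whole libraries Slc7a11 had 20.1 and 25.7 CPM. Slc3a2, the heavy chain partner of SLC7A11, was higher in the antibody library in tumour-like (log2 ratio 1.79), macrophage-like (1.87), neutrophil-like (1.75), CD8 T-like (2.24) and fibroblast-like cells (1.49). Transcript counts do not measure the antibody's action on the protein.

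A group of genes including Slc3a2 was higher in the antibody library whatever the cell class. Of 1469 genes with at least 20 counts in each of 5 classes, 70 had at least a 2-fold higher level in the antibody library in every class and 27 at least a 4-fold higher level. None was 2-fold lower in every class (0). If the classes were unrelated, 0.04 genes would be 2-fold higher in all of them. That figure is only a baseline, since all classes come from the same 2 libraries and their ratios are correlated. The genes included Cox5a, a respiratory chain subunit, the immediate early genes Junb and Ier2, Pfn1, an actin binding protein, Tpt1 and Fth1, the ferritin heavy chain. Cxcl9, Irf1, H2-D1, H2-Q4, H2-Aa, H2-Ab1 and Cd74, which belong to the interferon gamma and MHC lists, were among them too. Cox5a had log2 ratios of 5.61 in tumour-like, 5.53 in macrophage-like, 4.95 in neutrophil-like and 4.84 in fibroblast-like cells, and 5 control and 1375 antibody counts in CD8 T-like cells. Junb ranged from 4.34 in neutrophil-like to 5.36 in CD8 T-like cells, and Fth1 was at 3.39 in neutrophil-like and 3.75 in tumour-like cells. Across the 1469 genes, Pearson's r between the log2 ratios of any 2 classes lay between 0.508 and 0.861, where genes are not independent replicates. Because of this library-wide group, some values below are also given minus the same gene's median in the other classes. The median gene had a log2 ratio of -0.16 in tumour-like, -0.088 in CD8 T-like, -0.16 in macrophage-like, 0.020 in neutrophil-like and -0.17 in fibroblast-like cells.

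In tumour-like cells the comparison addressed the tumour's response to the antibody. Interferon gamma response genes were the most elevated list, with a median log2 ratio of 2.97 (interval 2.92 to 3.01), and 23 of 24 members were at least 2-fold higher. Minus the other classes, that median was 1.00. Cxcl9, a T cell attracting chemokine, had 46 control and 1904 antibody counts (log2 ratio 5.39), Iigp1, an interferon-induced GTPase, 4.18, and Gbp4, a guanylate binding protein, 3.83. The 1904 Cxcl9 counts were among 81914850 UMIs, against 9982 counts among 6442961 UMIs in antibody macrophage-like cells. Free RNA from macrophages was not excluded for this gene. Cd274, which encodes the checkpoint ligand PD-L1, had 5.88 and 64.3 CPM (3.45). MHC class I genes had a median of 1.78, with 14 of 16 members at least 2-fold higher, among them H2-D1 (2.21) and the peptide transporter Tap1 (2.96). Minus the other classes it was 0.76. Type I interferon genes had a median of 0.96, with all 24 members above 0 and 11 at least 2-fold higher, such as the nucleic acid sensor Zbp1 (2.25). T cell recruiting chemokines and cytokines had a median of 1.13, with 8 of 13 members at least 2-fold higher, including Cxcl10 (2.58) and Cxcl11 (2.92).

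Hypoxia and glycolysis genes were higher in antibody tumour-like cells by a median of 0.53, with 23 of 24 members above 0, such as Ero1a, an oxidase of the endoplasmic reticulum (1.93), and the glycolytic enzyme Hk2 (1.07). Ferroptosis genes had a median of 0.19 (99.65th percentile of 10000 matched random lists), 14 members above 0 and 9 below, with Fth1 at 3.75 and Gpx4, the glutathione peroxidase that reduces lipid peroxides, at -0.70. Glutathione and NRF2 genes had a median of -0.22 (37.3rd percentile), with Gsta4, a glutathione transferase, at -1.13. Amino acid stress genes, targets of ATF4, had a median of 0.018, with 12 members above 0 and 12 below: Ddit4, an mTORC1 inhibitor, was at 2.78 and Asns, asparagine synthetase, at -0.49. Proliferation genes had a median of -0.18 (50.1st percentile), close to the median gene. Nuclear-encoded oxidative phosphorylation genes had a median of -0.016, epithelial identity genes -0.32, mesenchymal genes 0.14 and apoptosis and p53 genes 0.13. Dissociation stress genes had a median of 0.97, with Junb and Ier2 (4.43) foremost, and 0.096 minus the other classes. Markers of other cells, a list meant to gauge free RNA, had a median of 0.39. The same 14 genes served for every class and include each class's own, such as Krt18 in tumour-like cells. The list is therefore no clean gauge of free RNA in any class.

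Under the fixed rule for named genes, 7 of the 10 highest ratios in tumour-like cells belonged to replication-dependent histones: H2ac8 (log2 ratio 7.89), H2ac20 (7.47), H2ac24 (7.32), H3c3 (7.28), H2ac10 (7.18), H3c6 (6.72) and H2ac18 (8 and 529 counts, interval 5.10 to 7.31). The others were Cox5a, H2ax (5.42), a histone variant, and Junb (5.31). In the other classes the same histone genes were also higher, with a median of 4.80 for H2ac8 and 5.78 for H2ac20. Near-identical histone copies can share reads, so single copies are uncertain. The lowest ratios were those of Pmepa1, a TGF-beta target (-2.66), Csn3, a casein (-2.61), Car6, a carbonic anhydrase (-2.31), Sapcd1 (-2.28), Prss12, a protease (-2.26), Ap3b2 (-1.88), Cela1 (-1.85), Tafa1 (-1.76), Serpinf1, an antiangiogenic factor (-1.72), and Acsbg1 (-1.69). Minus the other classes, Csn3 was at 0.55 and Prss12 at 0.37. Car6, Csn3 and Tafa1 also led clusters that held mostly control cells, and Cox5a, H2ax and H3c3 clusters that held mostly antibody cells.

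**Figure D2:**
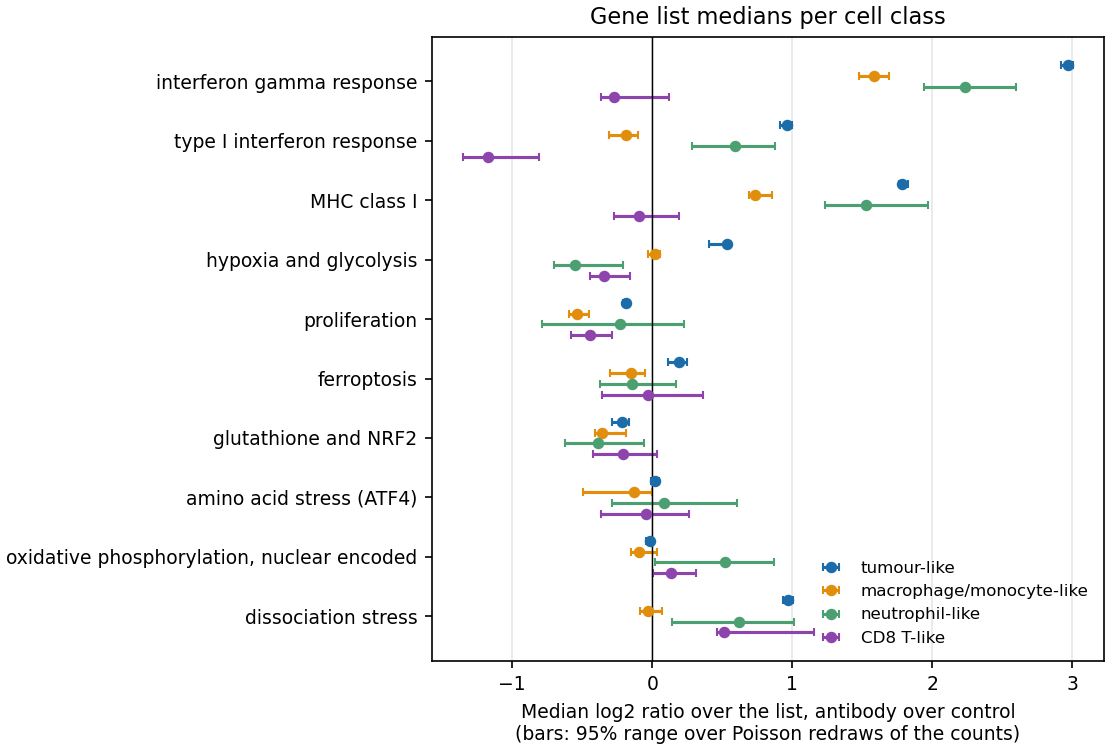
Median log2 ratio, antibody over control, of 10 gene lists in 4 cell classes (colours), 1 library per group, with 95% ranges over Poisson redraws of the counts. The interferon gamma list had medians of 2.97 in tumour-like, 1.58 in macrophage-like, 2.24 in neutrophil-like and -0.27 in CD8 T-like cells.

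In CD8 T-like cells the comparison asked how their state differed. Type I interferon genes were lower in the antibody library, with a median log2 ratio of -1.17 (interval -1.35 to -0.81), below all 10000 matched random lists, and 19 of 23 members below 0. Rsad2, an antiviral enzyme, was at -2.67 and Ifit3 at -1.79. T cluster 5, led by Ifit3, Isg15, Usp18, Rsad2 and Isg20, held 15 of 105 control and 27 of 479 antibody cells, and its part in these ratios was not tested. Interferon gamma response genes had a median of -0.27 and MHC class I genes -0.096. Cytotoxic effector genes had a median of -0.024, with members in both directions: the chemokines Ccl3 (2 and 2433 counts, 6.96, interval 5.43 to 10.33), Ccl5 (3.59) and Ccl4 (3.35) were higher, and the granzymes Gzmf (-2.58) and Gzmc (-2.42) lower. Both granzymes were lower still in the other classes, with medians of -4.79 and -3.58. Ifng was at 468 and 708 CPM (0.59, interval 0.30 to 0.90). Exhaustion genes had a median of 0.14 (96.6th percentile), with the checkpoint receptors Lag3 (3.86, and 2.85 in the other classes) and Havcr2 (1.15) higher and Cd244a (-1.42) lower. The exhaustion median has no settled direction, with an interval from -0.14 to 0.70. It was -0.066 with T subsets set by transcripts and -0.24 with cells thinned to 1000 UMIs. Minus the other classes it was -0.66, a value that does not bear on the direction by itself. T-like cells were more frequent in the antibody library, and free T cell RNA in the other classes was not excluded.

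Naive and memory genes in CD8 T-like cells had a median of 0.07, with the survival factor Bcl2 at -1.93 and the chromatin organiser Satb1 at 1.24, and T cell activation genes -0.11, with the costimulator Icos at 1.31. Proliferation genes had a median of -0.44, although the cycling T cluster 2 held 22 of 105 control and 143 of 479 antibody cells, with Stmn1 (-1.22) and Birc5 (-1.10) lower and Cdc20 (3.09, from 3 control counts, interval 1.75 to 5.60) higher. The remaining medians were -0.029 for ferroptosis, -0.21 for glutathione and NRF2, -0.042 for amino acid stress, -0.34 for hypoxia and glycolysis, 0.13 for oxidative phosphorylation, 0.43 for apoptosis and p53 (0.26 with genes at 0 counts set to their bound), 0.52 for dissociation stress and 1.20 for markers of other cells (-0.13 with no count minimum and -0.35 minus the other classes). By the fixed rule the highest ratios were those of Ccl3, Snrpf, a spliceosome protein (1 and 544 counts, 5.54, interval 3.64 to 11.43), Crlf2 (at least 2.86 on the log2 scale), Rnaseh2c (at least 2.78), Junb (5.36), Mpc2 (at least 2.74), Emc6 (at least 2.71), H1f4, a linker histone (1 and 415 counts, 5.15, interval 3.25 to 11.04), Cox5a (interval 3.91 to 6.76) and Tomm20 (2 and 581 counts, 4.90, interval 3.36 to 8.27). The lowest were Ifitm2 (-2.75), Fcer1g (-2.33), Cxcl10 (-1.96, but 0.051 with T subsets set by transcripts), Bcl2, Smyd3 (-1.88), Usp18, a brake on interferon signalling (-1.86), Isg20 (-1.85), Evl (-1.73), Pglyrp1 (-1.67) and Klrh1 (-1.67). The control sum rested on 217780 UMIs and the antibody sum on 1698061, and T cluster 4 held most control cells and T clusters 0 and 2 most antibody cells of this class. Several named genes also led these clusters, Ccl3 that of antibody cells and Ifitm2, Bcl2 and Pglyrp1 that of control cells.

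CD4 T-like and NK-like cells were under the minimum of 100 control cells and are described only. In the regulatory T-like CD4 cells, regulatory T genes had a median of -0.57, with 14 of 15 members below 0, such as the costimulatory receptor Tnfrsf18 (-1.21) and Foxp3 (-0.77). Type I interferon genes had a median of -1.63, exhaustion genes -0.54, Th1 genes -0.33, naive and memory genes -0.32, T cell activation genes -0.46 and cytotoxic genes 0.19. Proliferation genes had a median of 1.52 (1.39 with genes at 0 counts at their bound), against a median of 0.82 for matched random lists. Their other medians were -0.059 for interferon gamma response, -0.20 for MHC class I, -0.75 for ferroptosis, -0.043 for glutathione, 0.87 for amino acid stress, -0.77 for hypoxia, 0.53 for oxidative phosphorylation, 0.13 for apoptosis and 0.30 for dissociation stress. Th2 and Th17 lists had 2 measured genes each and the Tfh list 4, too few for a median, as had markers of other cells with 4. In NK-like cells cytotoxic genes had a median of -0.011.

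In macrophage-like cells the comparison addressed their activation state. MHC class II genes were higher in the antibody library, with a median log2 ratio of 1.72 (interval 1.68 to 2.35) and 7 of 9 members at least 2-fold higher, led by H2-Ab1 (3.18) and H2-Eb1 (2.77). The median was 0.89 without doublet removal. The cDC1 gene Xcr1 was detected in 0.25% of control and 11.4% of antibody cells of this class, so dendritic cells within it were not excluded as a source. Interferon gamma response genes had a median of 1.58, with 17 of 23 members at least 2-fold higher, including Cxcl9 (4.57) and Nos2, which makes nitric oxide (2.69). Minus the same gene's median in the other classes, the medians of both lists were -1.29 and -0.95. Not every other class was higher: in CD8 T-like cells the interferon gamma list was at -0.27 and H2-Ab1 at 1.98. Free RNA was not excluded as the source of MHC class II counts in the other classes, such as H2-Aa in tumour-like cells (5.40). The subtraction therefore does not show a weaker rise of this list in macrophage-like cells. Inflammatory genes had a median of -0.55, with 13 of 20 below 0, such as the cytokine genes Il1b (-1.46) and Ccl3 (-1.44). That median was -0.049 with each library clustered on its own, and -0.16 with unnamed clusters of high macrophage score counted in. Tissue repair genes went both ways around a median of -0.032, with the resistin-like gene Retnla at 5.25 (4.68 in the other classes) and the matrix proteins Spp1 at -2.42 and Fn1 at -2.16. Proliferation genes had a median of -0.53, below all random lists, with Mki67 at -0.97.

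MHC class I genes had a median of 0.74 in macrophage-like cells and T cell recruiting chemokines 0.29, but minus the other classes -0.51 and -1.08. The other medians were -0.19 for type I interferon (0.16 without doublet removal), -0.15 for ferroptosis, -0.36 for glutathione and NRF2, -0.13 for amino acid stress, 0.019 for hypoxia and glycolysis, -0.094 for oxidative phosphorylation, -0.028 for dissociation stress and 0.67 for markers of other cells. The last list includes Lyz2, Apoe and Cd74, which macrophages make themselves, so it does not gauge free RNA here. By the fixed rule the highest ratios were those of Tnik (0 and 149 counts, at least 4.68 on the log2 scale), Cox5a (5.53), H2aj (5.15), Xcr1, a chemokine receptor of cDC1 cells (3 and 215 counts, 4.99, interval 3.65 to 7.50), Crlf2 (4.89), Chchd10 (2 and 138 counts, 4.84, interval 3.28 to 8.22), Gtf2h4 (2 and 134 counts, 4.80, interval 3.23 to 8.18), Junb (4.74), Calhm6 (4.62) and Cxcl9. The lowest were Fcrls (-3.82), Rapsn (-2.99), Ltc4s, of leukotriene synthesis (-2.49), Gpr183 (-2.43), Spp1, Cd33 (-2.34), Trf (-2.30), Col14a1 (-2.26), Fn1 and Mgl2, a lectin of alternatively activated cells (-2.12).

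In neutrophil-like cells, interferon gamma response genes had a median log2 ratio of 2.24 (interval 1.94 to 2.60), with all 18 measured members at least 2-fold higher, such as Irf1 (3.30) and Gbp2b (3.24). Minus the other classes, that median was 0.33, and those of inflammatory and dissociation stress genes turned to -0.16 and -0.13. MHC class I genes had a median of 1.53 and type I interferon genes 0.59, with 20 of 21 members above 0. Hypoxia and glycolysis genes had a median of -0.55, with the glucose transporter Slc2a1 at -0.88, and inflammatory genes 0.19. The chemotaxis and protumour list had a median of -0.24, with Cd274 at 2.12 and Hilpda at -1.59. The other medians were -0.14 for ferroptosis, -0.39 for glutathione and NRF2, 0.085 for amino acid stress, -0.23 for proliferation, 0.52 for oxidative phosphorylation, 0.62 for dissociation stress and 0.30 for markers of other cells, and the granule list had 3 measured genes. By the fixed rule the highest ratios were those of Junb (4.34), Pfn1 (4.17), Ccl8 (3.98), Fth1 (3.39), Irf1, Gbp2b, Itm2b (3.17), Tpt1 (3.16), Ier2 (3.06) and Lrg1 (2.87). The lowest were Retnlg (-2.51), Cyp4f18 (-1.84), Dhrs9 (-1.79), Ccl6 (-1.61), Hilpda, Steap4 (-1.58), Cxcl3 (-1.55), Plin2 (-1.29), Wfdc17 (-1.21) and Lilrb4a (-1.21). Neutrophil-like cells were shallow, with medians of 658.5 and 755 UMIs, and Ccl6, Hilpda, Plin2, Wfdc17 and Lilrb4a had the opposite direction under the stricter cell filter. So had the lists of hypoxia and glycolysis (0.17), chemotaxis and protumour (0.81) and oxidative phosphorylation (-0.091), which also turned without doublet removal (0.029, 0.39 and -0.10).

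**Figure D3:**
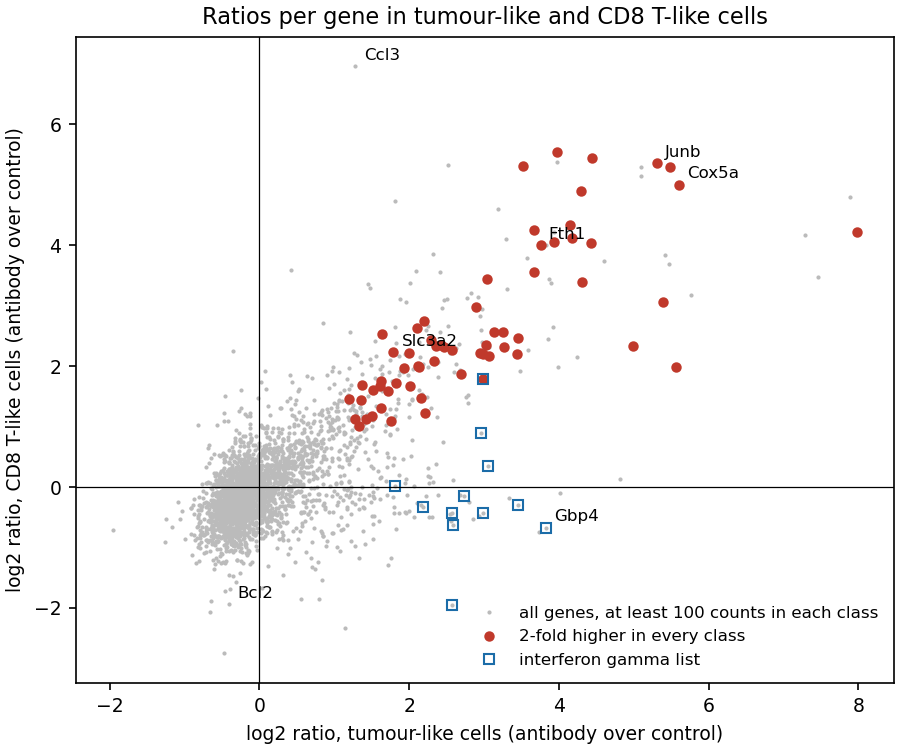
Log2 ratio, antibody over control, of each gene in tumour-like (x axis) and CD8 T-like cells (y axis), 1 library per group, for genes with at least 100 counts in each class. Red points are genes at least 2-fold higher in every class, such as Junb (5.31 and 5.36), and open squares the interferon gamma list, such as Gbp4 (3.83 and -0.67).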

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

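All tests of explanations in this part were chosen only after the result they weigh was seen.

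Some signals lay outside the main measurement and stood above the control library. Reg1 had 0 control counts and 355 antibody counts, of which 299 sat in 12 fibroblast-like cells. H2ac22 had 354, Igkv1-88 109 and Rps2-ps7 104 antibody counts against 0. Unnamed clusters held a larger share of the antibody library: cluster 6, decorin-high, 13.1%, cluster 7, hypoxia-led, 6.46%, cluster 10, low in UMIs, 6.40%, cluster 11, led by Il1b and Lyz2 with MHC class II genes, 5.85%, cluster 15, low in UMIs and led by Lyz2 and C1q genes, 2.84%, and cluster 21, low in UMIs with T cell genes, 0.808%. Cluster 6 has a control counterpart, cluster 4, so its excess is not an excess of decorin-high cells. Rn18s-rs5, which holds 18S ribosomal RNA sequence, was 2.15 higher on the log2 scale over the whole antibody library.

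In other results classes went in opposite directions, and the difference between classes was not tested. Type I interferon genes had medians of 0.96 in tumour-like and 0.59 in neutrophil-like cells and -1.17 in CD8 T-like cells. Hypoxia and glycolysis genes had medians of 0.53 in tumour-like and -0.55 in neutrophil-like cells, but the latter was 0.17 under the stricter cell filter and 0.029 without doublet removal, so this opposition does not hold there.

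For the genes higher in every class, free RNA from tumour cells would leave levels far lower in CD8 T-like than in tumour-like cells. Their median level in CD8 T-like cells was 0.947 of the tumour-like level, against 0.056 for tumour markers. These genes were selected by a count minimum and a 2-fold rise in every class, which favours genes with high levels in CD8 T-like cells. The contrast therefore does not decide on free RNA from tumour cells, and a median does not clear each member. Length or GC bias would shift other genes of like length and GC content as well, but those had a median log2 ratio of -0.15 in tumour-like cells, and 0.35 at most in any bin, against 2.58 for the 69 genes with a known transcript. This replaced an earlier form of the test, which asked whether the genes stayed 2-fold higher after correction and was dropped because their selection fixed its outcome. Exact shared sequence is no better an account, since 18.8% of them shared a 31-base sequence near the 3' end with another gene, against 19.4% of other genes. The annotation searched may differ from the one behind the counts. Copies annotated only in the latter, and inexact or more upstream matches, were not tested. Free RNA from macrophages was not tested for this group, which includes Apoe, C1qc, Cd74 and Ccl8, and stays open for such genes. A difference in handling, library preparation or annotation between the libraries stays open, as does the antibody, since each group is 1 library and the shift in 18S sequence and histone genes falls on the same side.

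For the interferon gamma genes, the library-wide shift would raise them in CD8 T-like cells as well, where their median was -0.27 against 2.97 in tumour-like cells. Free RNA from macrophages would leave them far below the macrophage-like level, but their median tumour-like level was 0.741 of it, against 0.008 for 12 macrophage markers, chosen without Spp1, Ctsb, Cd68 and Apoe. A median does not clear each member, and for Cxcl9 free RNA from macrophages was not excluded. Among lists matched on length and GC content their tumour-like median lay at the 100th percentile. A response to interferon gamma in tumour-like and myeloid cells stays a candidate explanation, which 1 library per group leaves confounded with the animal and its handling.

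Decorin-high cells without Y-linked transcripts had 2.14 CPM of these (interval 1.59 to 2.83), against 86.8 CPM in fibroblast-like cells. Naming alone put them under a cut of 33.4 CPM, but their level lies far below that cut, which argues against host fibroblasts; the bounds of this test were reset to lie under the cut after its value was seen. Fibroblast RNA or doublets would bring Col1a1 along with Dcn, but the ratio of the former to the latter was 0.823% of that in fibroblast-like cells. The tumour line stays open as an origin, since tumour markers separate the classes poorly. Their median level was 43.0 CPM in decorin-high, 37.4 CPM in fibroblast-like and 81.5 CPM in tumour-like cells. The test used the median of per-gene ratios to the tumour-like level, where decorin-high cells, at 42.6%, lay below the 51.8% of fibroblast-like cells. As initially written, that test counted the 42.6% against the tumour line, and its rule was changed after the value was seen.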

How the results depend on the processing

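No paired analysis was possible because each group has 1 library. Which results count as main was settled after list medians had been seen. Under the settings chosen in advance, 684 of 698 values of named genes, 452 of 510 list medians and 54 of 59 shares kept their sign. Under settings chosen after seeing the data, 116 of 130, 66 of 88 and 2 of 3 did. For NK-like cells and for clusters with Y-linked transcripts, the log2 ratio of the share stayed inside its reported interval under each change of filter or clustering. Shallow classes limit depth: CD8 T-like, neutrophil-like and CD4 T-like control sums rest on few UMIs, so genes of low level were not measured there. The cause was not tested for any of the following shifts, except where the construction is named.

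Under the stricter cell filter the log2 ratios of shares were -0.35 for tumour-like, 2.64 for T-like, 2.72 for CD8 T-like, -0.27 for neutrophil-like and 1.59 for fibroblast-like cells, and 0.34 for CD4 among T-like cells. Medians were 2.90 for interferon gamma in tumour-like and 2.91 in neutrophil-like cells, and -0.28 for proliferation in tumour-like cells. In neutrophil-like cells hypoxia became 0.17, oxidative phosphorylation -0.091, chemotaxis and protumour 0.81, Ccl6 0.43, Hilpda 0.82, Plin2 0.061, Wfdc17 0.12 and Lilrb4a 0.69.

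Without doublet removal, shares were at -0.50 for tumour-like, -0.43 for macrophage-like and -0.18 for fibroblast-like cells. In tumour-like cells type I interferon was 1.01, MHC class I 1.76 and proliferation -0.31. In macrophage-like cells interferon gamma was 1.82, MHC class II 0.89, inflammatory genes -0.78 and type I interferon 0.16. In neutrophil-like cells interferon gamma was 2.70, hypoxia 0.029, oxidative phosphorylation -0.10 and chemotaxis and protumour 0.39.

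At resolution 2 the tumour-like share was -0.46 and proliferation -0.29. With each library clustered on its own, shares were -0.36 for tumour-like, 1.99 for T-like, 0.63 for macrophage-like, 2.20 for fibroblast-like and -0.024 for CD4 T-like cells, and -2.01 for CD4 among T-like cells. Tumour-like medians were 0.91 for type I interferon, 2.89 for interferon gamma, 1.72 for MHC class I, -0.30 for proliferation and 0.56 for hypoxia, and macrophage-like medians 1.77 for interferon gamma and -0.049 for inflammatory genes. No CD8 T-like cells were named in the control library then (0, against 468), so that setting gave no value for them.

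With unnamed clusters without Y-linked transcripts counted as tumour-like, chosen after seeing the data, the share was -0.38, MHC class I 1.75 and proliferation -0.26. With unnamed clusters whose best or second score was macrophage counted as macrophage-like, also chosen later and including a cluster whose leading genes hold more markers of another class, the share was 1.00, interferon gamma 1.71, MHC class II 1.57 and inflammatory genes -0.16. With decorin-high clusters counted as fibroblast-like, also chosen later, that share was -0.094. These settings change which cells are counted.

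With cells thinned to 1000 UMIs, exhaustion in CD8 T-like cells was -0.24, interferon gamma 2.60 in tumour-like and 1.71 in macrophage-like cells, and in tumour-like cells MHC class I 1.59, proliferation -0.065 and hypoxia 0.30. Neutrophil-like cells left 11 and 29 cells and gave no value. Epithelial identity was left with 4 genes.

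Minus the other classes, chosen after seeing the data, exhaustion in CD8 T-like cells was -0.66, type I interferon -1.61 and interferon gamma -2.42, with markers of other cells -0.35 and Cox5a -0.24. In tumour-like cells interferon gamma was 1.00, MHC class I 0.76, amino acid stress 0.33, proliferation 0.30, glutathione 0.11, mesenchymal genes -0.20, Csn3 0.55, Prss12 0.37 and Slc3a2 -0.018. In macrophage-like cells interferon gamma was -0.95, MHC class I -0.51, MHC class II -1.29, inflammatory genes -1.32, recruiting chemokines -1.08, ferroptosis 0.018, glutathione 0.037 and Junb -0.36. In neutrophil-like cells interferon gamma was 0.33, inflammatory genes -0.16, dissociation stress -0.13, Junb -0.77, Fth1 -0.50, Tpt1 -0.41, Ier2 -0.72, Lrg1 -0.21 and Slc3a2 -0.085, and in fibroblast-like cells Slc3a2 was -0.34. List medians within counting error of 0 also changed sign: naive and memory (-1.15), ferroptosis (0.016), glutathione (0.015) and amino acid stress (0.17) in CD8 T-like cells, and amino acid stress (-0.30) and markers of other cells (-0.40) in neutrophil-like cells. By construction this removes what other classes share, so a response shared by several classes shrinks too. For genes that the other classes hardly make, the ratios subtracted may come from free RNA, which was not tested.

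Median-of-ratios scaling moved tumour-like medians by construction to 0.36 for ferroptosis, 0.18 for amino acid stress, 1.13 for type I interferon, 3.14 for interferon gamma, 1.95 for MHC class I, -0.020 for proliferation and 0.70 for hypoxia, and macrophage-like ones to 1.74 for interferon gamma and 0.011 for ferroptosis. Without mitochondrial, ribosomal and haemoglobin genes in the total, amino acid stress was -0.024, MHC class I 1.74 and proliferation -0.23 in tumour-like cells. At a count minimum of 100, hypoxia in tumour-like cells was 0.37, and with none, markers of other cells in CD8 T-like cells were -0.13. With T subsets by transcripts, Cxcl10 in CD8 T-like cells was 0.051. At the minimum of 100, lists of naive and memory genes and markers of other cells in CD8 T-like cells, and of amino acid stress, MHC class I, proliferation, oxidative phosphorylation and markers of other cells in neutrophil-like cells, kept under 5 genes and gave no value.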

Other observations

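The Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty together had 234 CPM in CD8 T-like, 124 CPM in macrophage-like and 114 CPM in endothelial-like cells, and 1.24 CPM in tumour-like cells, over both libraries. Decorin-high cells without them carried 5896 CPM of Dcn and 104 CPM of Col1a1, against 3114 and 6694 CPM in fibroblast-like cells. Their share was 15.3% of control and 13.5% of antibody cells. Spp1 had 16262 and 9362 CPM in tumour-like cells and 5069 and 944 CPM in macrophage-like cells.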
